A study of Mus musculus with 12 samples.

How the data were processed

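RNA was measured in the epithelium of the urogenital sinus of C57BL/6J mouse embryos at embryonic day 15.5. The 12 libraries form the groups Control (4 libraries, wildtype) and Dnmt1cKO (8 libraries, in which a Cre recombinase under the control of Shh deleted Dnmt1 in this epithelium). Per the labels' protocols, trypsin was used to free the epithelium from the stroma, and tissue of several embryos was pooled into a single lysate for each harvest batch. Polyadenylated RNA was selected and fragmented, the first cDNA strand was primed with random hexamers that carried an adaptor, the other adaptor was ligated to the single-stranded cDNA, and the product was amplified by PCR. No molecular identifiers are mentioned, so repeated reads of a molecule cannot be told from separate molecules, and intervals and floors that rest on counts cover counting error only.

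The deposited table holds RSEM expected counts for 20308 gene symbols in the 12 libraries, which are estimated counts in which the authors' software divided reads that fit several genes or transcripts. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, Bowtie 0.12.9 and RSEM 1.2.3, with the mouse build mm10; trimming, mapping parameters and the annotation are not given in the sources used here. Of the genes in the table, 38.5% had a fractional value in at least 1 library, and 4471 had no count in any library. The expected counts were rounded to whole numbers before each count test. Whether strand was used in counting is not given, so overlapping and antisense genes, and members of families with near-identical copies, are uncertain.

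Sample groups were taken from the genotype labels. Sample descriptions also carry a code made of the letter b and a number, whose meaning the labels do not state. Controls 1 to 4 carry the codes 4, 5, 6 and 7, and Dnmt1cKO 1 to 8 carry 2, 3, 4, 5, 6, 7, 7 and 7. Whether the 3 Dnmt1cKO libraries with code 7 came from separate pools of embryos is not stated, so the spread between them may be technical, and p-values measure the spread between these libraries. No pair of libraries within a group matched within counting noise: the lowest chi-square per degree of freedom between libraries of a group was 28.1, so no library was counted as a repeat of another. This measure cannot tell separate pools of embryos from separate libraries made of 1 lysate.

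The comparison of Dnmt1cKO with Control used the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term, TMM scaling factors, robust dispersion estimates, and the filterByExpr filter with a minimum count of 10 and a minimum total count of 15. P-values were adjusted by the Benjamini-Hochberg method over all 12761 genes tested, and an adjusted p under 0.05 was called. Levels per library are CPM, the counts of a gene scaled to the TMM-adjusted total of its library. Log2 fold changes are Dnmt1cKO against Control with their standard errors (SE), and levels are means with standard deviations (SD). The square root of the common dispersion, which is the coefficient of variation between libraries, was 0.984. A ratio against a group in which every library was at 0 was computed as a lower bound, with 3 counts over the whole group as the floor, and a ratio against 1 to 3 counts is given with an exact 95% counting interval. Levels of Dnmt1 in each library carry exact Poisson 95% intervals, and the difference in its mean log2 CPM (pseudocount 2) was tested with an exact two-sided permutation test.

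Before the data were examined, 23 gene lists, the main test, the alternatives and the rule for named genes were fixed. The lists were imprinted genes, germline genes whose promoters are methylated in somatic cells, p53 target genes, interferon-stimulated genes, clustered protocadherins, the DNA methylation machinery, proliferation genes, DNA damage repair genes, apoptosis genes, basal epithelial markers, luminal and urothelial markers, prostatic bud genes, androgen and steroid pathway genes, epithelial adhesion genes, and markers of stromal, endothelial, immune, erythroid, and neural and glial cells, of the Wolffian and Mullerian ducts and of hindgut epithelium, dissociation stress genes and sex-linked genes. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the 21 lists tested. Camera compares a list with all other genes. Hindgut markers had fewer than 5 tested members and got no list test, and sex-linked genes were planned without one. The list tests were repeated with a correlation estimated per list, with fry, which asks whether the members of a list move on balance in 1 direction, and with its mixed form, which asks whether they change in either direction.

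Named genes were chosen by a fixed rule. It took Dnmt1; the 10 genes with the largest change in each direction among called genes with a mean log2 CPM of at least 1 whose groups did not overlap; up to 4 called members per list in its majority direction by smallest p and up to 2 in the other direction, or the 2 members with the highest mean CPM where none was called; and a panel of genes given with whatever value they had. The panel genes Xist and H19 are not analysed here, and some other panel genes are not reported here. Any other gene named was chosen after its values were seen.

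Gene coordinates are from the GENCODE M21 annotation of GRCm38, which is the build mm10, as 1-based gene spans; gene-level counts do not resolve exons, introns or untranslated regions. Chromosomes for the test of X-linked genes came from the RefSeq gene table of the same build, which placed 12724 of the 12761 genes tested.

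The tests were first tried on simulated counts drawn from the means and library sizes of these libraries, 8 against 4, over 12354 genes. The edgeR test recovered 10.4% of genes changed 4-fold, 46.3% of those changed 16-fold and 63.6% of those changed 64-fold, and 4.3% of its calls were false. DESeq2 recovered 25.4%, 71.6% and 77.3%, with 27% of its calls false, and limma-voom with quality weights recovered 4.48%, 44.8% and 56.1%, with 5.13% false. Apart from the changed genes, all simulated libraries shared the same mean level per gene, scaled to their size. None was simulated with low complexity, so these shares of false calls do not carry over to the real calls.

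The alternatives fixed beforehand were DESeq2 1.42.0; limma-voom with library quality weights; RLE scaling; library totals alone; no filter on low counts; a filter of at least 1 CPM in at least 4 libraries; unrounded expected counts; a test against a 1.5-fold change; a minimum log2 change of 1; the title number or the b code as a block; libraries with codes 4 to 7 alone; the 3 Dnmt1cKO libraries with code 7 summed; the mean log2 CPM of the stromal markers as a covariate; and each library left out in turn. After the data were examined, 2 alternatives were added, which left out Control 3 and the library labelled Control 4, or these, Control 2 and Dnmt1cKO 2. Other groupings of the 12 libraries into 4 and 8 were tested in 100 of the 495 possible splits, the real one included. No column of per-sample values was left out, and the text that trails the table's header was not used.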

Results

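Gene expression was measured in the epithelium of the urogenital sinus, the embryonic tube that gives rise to the bladder neck, urethra and prostate, at embryonic day 15.5 in mice. The 4 Control libraries came from wildtype embryos, and the 8 Dnmt1cKO libraries came from embryos in which Cre recombinase driven by Shh, a gene of this epithelium, deleted Dnmt1. DNA methyltransferase 1, the product of Dnmt1, copies methylation marks to the new DNA strand after replication. The question was which transcripts differ in the epithelium once this enzyme is deleted.

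Depth differed widely between libraries. Controls 1, 2 and 3 and the library labelled Control 4 held 7577706, 2915193, 1613514 and 543591 expected counts, and the Dnmt1cKO libraries held 4007533 to 11970907. At least 1 count was found for 13116, 10753, 9097 and 6744 genes in these 4 libraries in the same order, for 10205 genes in Dnmt1cKO 2 and for 12735 to 13837 genes in the other Dnmt1cKO libraries. When every library was thinned to the depth of the shallowest, Control 1 held 12188 genes and Control 3 held 7663, against 9318 to 12599 genes in the Dnmt1cKO libraries, so depth alone did not account for the difference in genes detected. The first principal component of log2 CPM, with 41.7% of the variance, set the library labelled Control 4 (365.7) and Control 3 (208.3) apart from all other libraries (-87.6 to 18.3).

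**Figure D1:**
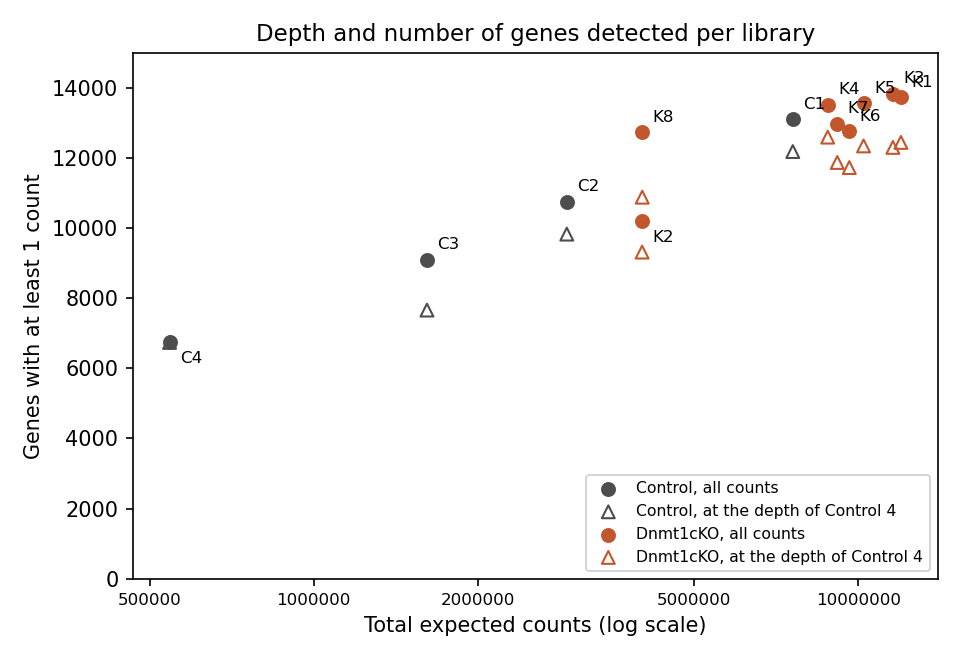
Total expected counts per library (horizontal axis, log scale) against the number of genes with at least 1 count (vertical axis), for Control (C) and Dnmt1cKO (K) libraries; filled circles use all counts and open triangles use counts thinned to the depth of the shallowest library. Control 3 and the library labelled Control 4 (C3, C4) held 9097 and 6744 genes, fewer than any other library.

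Transcripts of the deleted gene were present in every library. Dnmt1 (chromosome 9, 20907209 to 20959888, minus strand) stood at 97.0, 42.7, 22.8, 63.2, 73.0, 35.0, 58.6 and 35.9 CPM in Dnmt1cKO 1 to 8, and at 164, 114 and 237 CPM in Controls 1 to 3. In the library labelled Control 4 it stood at 2.84 CPM, which was a single count (1 count, exact Poisson 95% interval 0.072 to 15.8 CPM), below every Dnmt1cKO library and against its label. The group means were 53.5 ± 24.2 CPM (SD, n = 8) in Dnmt1cKO and 129 ± 98.3 CPM (SD, n = 4) in Control, and the log2 fold change of -1.29 ± 0.63 (SE) did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.284). The difference in mean log2 CPM had an exact two-sided permutation p of 0.794 over the 495 splits of the 12 libraries. Without the library labelled Control 4, the only one left out in this test, it was 0.00606 over 165 splits. Controls 1 to 3 all lay above every Dnmt1cKO library, so this is the lowest p that 165 splits can give. The omission fixed that result, which adds no support for a fall in Dnmt1. Without that library edgeR with Benjamini-Hochberg adjustment gave a log2 fold change of -1.60 with adjusted p = 0.0815, the lowest of its alternatives. With the stromal level as a covariate the log2 fold change was -0.024 (edgeR, Benjamini-Hochberg adjusted p = 0.992). Within the codes 4, 5, 6 and 7 that both groups share, Dnmt1cKO differed from Control by -2.83, -0.85, -1.69 and 3.76 on the log2 scale. Counts are per gene and cover all exons, and the deleted exons are not given in the sources used here, so remaining transcripts do not show whether the deletion took place in a cell.

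**Figure D2:**
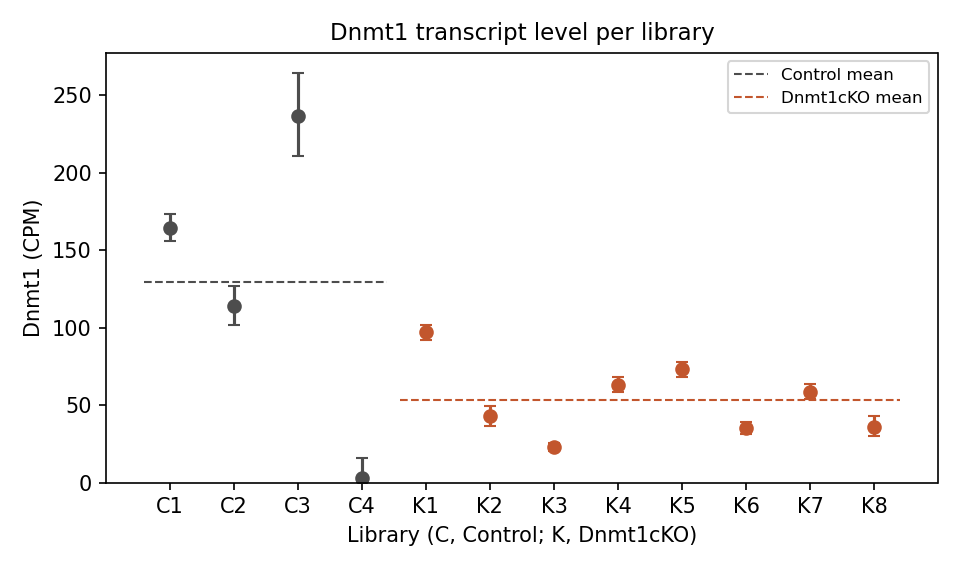
Dnmt1 level per library in CPM (vertical axis) for the Control (C) and Dnmt1cKO (K) libraries, with exact Poisson 95% intervals that cover counting error only; dashed lines are group means of 129 and 53.5 CPM. The library labelled Control 4 (C4) sits at 2.84 CPM, under all 8 Dnmt1cKO libraries.

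Among called genes whose groups did not overlap and whose mean level passed the minimum set for named genes, the 10 with the largest fitted log2 fold change upward had no count in any Control library. Sycp1 and Syce1, which build the synaptonemal complex that joins chromosomes in meiosis, were at least 312-fold and 241-fold higher, and Zscan4d and Tcstv1, genes of the early cleavage embryo, at least 419-fold and 142-fold higher. Gpat2, a glycerol-3-phosphate acyltransferase of germ cells, was at least 90.8-fold higher, and Clca4, Xlr5a, Pet2, Usp17la and Serpina3i were at least 123-fold to 188-fold higher. Without Control 1, which holds most of the Control counts, such bounds stand at 36.3% of their size. Zscan4d, Tcstv1, Xlr5a, Usp17la, Serpina3i and Clca4 belong to families of near-identical copies and their levels are uncertain. Among the genes that fell most were Clrn1, which encodes a membrane protein needed by sensory hair cells, Rhox8, an X-linked homeobox gene, and Emp2, an epithelial membrane protein, which were 153-fold, 34.8-fold and 6.01-fold lower. Together with these, D3Bwg0562e, Tef, Fkbpl, Amer1, Eif4e3, Cc2d2a and Inpp5a were the 10 genes with the largest fall, from 5.87-fold to 153-fold, among those without overlap between the groups. Without the library labelled Control 4 the fall was 74.7-fold for Clrn1, 1.95-fold for Emp2, 4.74-fold for Amer1, 4.45-fold for Tef, 4.12-fold for Eif4e3, 3.03-fold for Cc2d2a, 2.09-fold for Fkbpl and 1.8-fold for Inpp5a. Without Control 3 it was 15.5-fold for Rhox8 and 5.43-fold, from 25.5-fold, for D3Bwg0562e, which fell 38.7-fold without Dnmt1cKO 8. Without the library labelled Control 4 the adjusted p of Zscan4d, Tef, Fkbpl, Eif4e3, Cc2d2a, Emp2 and Inpp5a was 0.102 to 0.549 (edgeR, Benjamini-Hochberg), without Control 3 that of D3Bwg0562e was 0.299, and Serpina3i lost its call without Control 2, Control 3 or the library labelled Control 4 (0.0541 to 0.133).

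In all, 132 genes rose and 198 fell of 12761 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 2263 had an unadjusted p under 0.05. Of the 132 higher genes, 63 had no count in any Control library and 88 had at most 3 counts over all of them. All Dnmt1cKO libraries lay above all Control libraries for 83 of the higher genes and below them for 22 of the lower genes. Over all 12761 genes tested, 331 lay wholly above and 62 wholly below. Chance would put 0.202% of genes in each of these patterns if the libraries were interchangeable. Control 3 and the library labelled Control 4, with the fewest genes detected, are not, so neither count can be read against that share. Each of the 198 lower genes had its highest level in the library labelled Control 4 (164 genes) or in Control 3 (34 genes), and Controls 1 and 2 both lay above every Dnmt1cKO library for 41 of them. Without these libraries, an alternative chosen after the data were examined, 45 genes rose, 39 of them among the 132, and 2 fell, 0 of them among the 198, with 974 and 310 genes at an unadjusted p under 0.05 in edgeR. Control 1 against the 7 Dnmt1cKO libraries other than Dnmt1cKO 2 gave 46 higher genes, 38 of them shared, and 0 lower, with 260 lower at an unadjusted p under 0.05 in edgeR. Within the codes 4, 5, 6 and 7 the 132 genes were higher in 130, 132, 132 and 132 cases, and the 198 genes were lower in 158, 158, 169 and 185. These genes were called from the same libraries, so the selection largely set these directions.

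The median log2 fold change of all tested genes was 0.22, and 0.072 and 0.38 with RLE factors and with library totals alone, and the list tests compare each list with all other genes. Of the called genes 40% were higher, against 19% with RLE factors (170 higher, 726 lower) and 70.6% with library totals alone (113 higher, 47 lower). DESeq2 called 487 higher and 1030 lower, and limma-voom with quality weights 7 and 25. Leaving out Control 1, Control 2, Control 3 or the library labelled Control 4 gave 657, 121, 128 and 60 higher genes and 494, 405, 308 and 36 lower genes. The lower genes numbered 103, 100, 115, 95, 124 and 111 without Dnmt1cKO 1, 3, 4, 5, 6 and 7. 

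Germline genes, which are active in germ cells and carry methylated promoters in somatic tissue, had more members that rose (26) than any other of the 23 lists. Taf7l, a testis form of a general transcription factor subunit (X chromosome, 134460118 to 134476490), stood at 275 ± 83.5 CPM in Dnmt1cKO (SD, n = 8) against 3 counts over the 4 Control libraries, a ratio of 1182 (95% counting interval 404 to 5730). Dazl, an RNA-binding protein required for germ cell development (chromosome 17, 50279395 to 50293636), stood at 192 ± 39.2 CPM against 2.41 ± 4.43 CPM (SD, n = 8 and 4), 84.4-fold higher. It was 690-fold higher without Control 3, which stood at 9.05 CPM, and 55.7-fold without Control 1. Tex19.1, which restrains mobile elements in germ cells (chromosome 11, 121146143 to 121148319), was 153-fold higher, or 242-fold without Control 2, and Sycp1 (chromosome 3, 102818499 to 102936100) stood at 74.6 ± 29.8 CPM against 0 counts in Control. All 4 were higher in each of the 8 Dnmt1cKO libraries than in any Control library, with adjusted p from 1.88e-09 to 4.04e-05 (edgeR quasi-likelihood, Benjamini-Hochberg).

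Of the 55 germline genes tested, 26 rose and 0 fell over all genes in edgeR, with 1 lower at an unadjusted p under 0.05 and 0 called lower by DESeq2 and limma-voom; with RLE factors edgeR called 30 higher and 1 lower. Adjusted over the list alone, 41 rose and 1 fell, Mei4, which acts in meiotic recombination and was named after its value was seen. The median log2 fold change was 6.65, or 4.78 with genes at 0 in Control set to their bound, and camera gave an adjusted p of 8.94e-30 (adjusted p = 0.0139 with an estimated correlation). Within the codes 4, 5, 6 and 7, 52, 54, 50 and 52 of the 55 members were higher in Dnmt1cKO, and 47 in all of them. The share of all tested genes that was higher within each code was not computed. Without Control 3 and the library labelled Control 4, 16 members were called, and 18 without the latter alone; limma-voom with quality weights called 4 and DESeq2 35. Members of the Rhox, Xlr, Mage, Tuba3 and Nlrp4 families are copies that share reads, and 9 of the 26 belong to them.

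**Figure D3:**
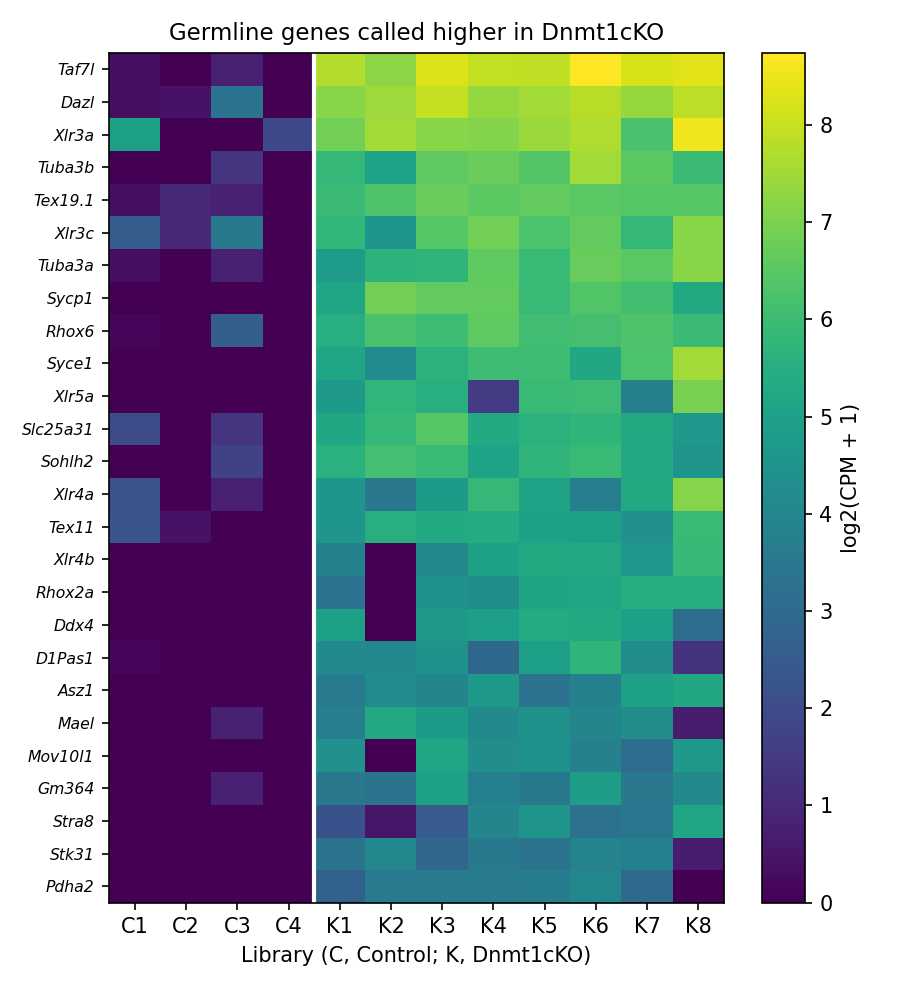
Levels of the 26 germline genes that rose in Dnmt1cKO, as log2(CPM + 1) on a colour scale, one line per gene and one column per Control (C) or Dnmt1cKO (K) library. Control columns, among them the library labelled Control 4, are dark for most genes and Dnmt1cKO columns are bright.

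Genes activated by the p53 protein rose as a list in camera (45 tested, median log2 fold change 0.94, adjusted p = 0.000312), and did not pass with an estimated correlation (adjusted p = 0.412). Pmaip1, which encodes the cell death protein Noxa (chromosome 18, 66458533 to 66465565), stood at 163 ± 69.3 CPM in Dnmt1cKO (SD, n = 8) against 5.97 ± 9.11 CPM in Control (SD, n = 4), 22.9-fold higher. Cdkn1a, the cell cycle inhibitor p21, was 14.8-fold higher, Ccng1, which encodes cyclin G1, 7.47-fold, and Trp53inp1, a p53-induced nuclear protein, 5.12-fold. In edgeR with Benjamini-Hochberg adjustment the adjusted p was 0.00125 for Pmaip1, 0.0232 for Cdkn1a, 0.00747 for Ccng1 and 0.0205 for Trp53inp1, and all 8 Dnmt1cKO libraries lay above all 4 Control libraries for each. Of 45 members tested, these 4 rose and 0 fell, over all genes and adjusted over the list alone, and edgeR gave 8 higher and 0 lower at an unadjusted p under 0.05, DESeq2 5 higher and limma-voom 0. Mdm2, which restrains p53, and Trp53 itself had log2 fold changes of 1.496 and 0.37 and did not pass the test.

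Without Control 1 the rise was 78.5-fold for Pmaip1, 26.7-fold for Cdkn1a and 11.9-fold for Ccng1. Control 1, the deepest Control, held the highest Control level of each, at 19.4, 8.61 and 89.9 CPM. The Dnmt1cKO means were 163, 66.4 and 322 CPM. Ccng1 stood at 66.1 CPM in Control 2, 6.03 CPM in Control 3 and 2.84 CPM in the library labelled Control 4. The size of its rise thus depended on the Controls kept. Leaving out the library labelled Control 4 raised the adjusted p of Cdkn1a to 0.0506 (edgeR, Benjamini-Hochberg), and the other 3 genes stayed called without it and without both it and Control 3. Within the codes 4, 5, 6 and 7, 35, 29, 35 and 40 of the 45 p53 targets were higher in Dnmt1cKO, and 18 in all of them. With the code as a block in edgeR, the median log2 fold change of all tested genes was 1.09. The share of all tested genes that was higher within each code was not computed. These counts therefore do not set p53 targets apart from other genes. For code 7 the only Control is the library labelled Control 4.

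**Figure D4:**
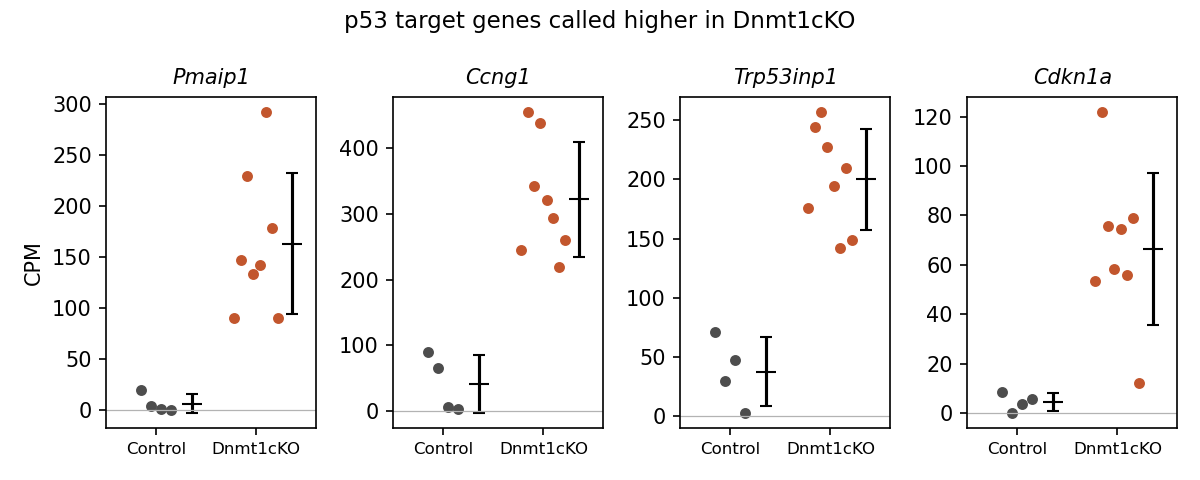
CPM (vertical axes, each from its own scale) of the p53 target genes Pmaip1, Ccng1, Trp53inp1 and Cdkn1a in the 4 Control and 8 Dnmt1cKO libraries; points are libraries, and the bar beside them is the mean with its SD. Pmaip1 spans 89.9 to 292 CPM in Dnmt1cKO and 0 to 19.4 CPM in Control, which includes the library labelled Control 4.

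Other stress and cell cycle lists had at most 2 called members each. Samd9l, an antiviral gene induced by interferon, rose against a single count in Control (ratio 269, 95% counting interval 48.2 to 10637). It was the 1 of 37 interferon-stimulated genes called, with 2 higher and 0 lower adjusted over the list alone. In edgeR 10 were higher and 0 lower at an unadjusted p under 0.05, DESeq2 called 4 higher and 1 lower, and limma-voom 0. This list passed camera as higher (median log2 fold change 0.70, adjusted p = 0.0417, and 0.418 with an estimated correlation). It did not pass camera with the stromal level as a covariate (adjusted p = 0.313). Nor did it pass without Control 1, Control 3 or Dnmt1cKO 3, 5, 6 or 7 (camera adjusted p = 0.0519 to 0.289). Proliferation genes, which drive DNA replication and mitosis, also passed as a list (50 tested, median 0.57, adjusted p = 0.0316; adjusted p = 0.697 with an estimated correlation). None of the 50 was called in edgeR over all genes or adjusted over the list alone; 4 were higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 1 higher and 2 lower, and limma-voom 0. Mki67, Top2a and Hmgb2 had log2 fold changes of 0.25, 0.19 and -0.10, that of Hmgb2 being 0.15 with library totals alone, and those of Mki67 and Top2a -0.060 and -0.12 without the library labelled Control 4. Within the codes 4, 5, 6 and 7, 37, 32, 32 and 41 proliferation genes were higher. The share of all tested genes within each code was not computed, so these counts do not set proliferation genes apart from other genes. Among 44 DNA damage repair genes Lig1, which joins nicks in replicated DNA, fell 5.38-fold, with 1 lower adjusted over the list alone and camera adjusted p = 0.588; it was 2.09-fold lower with adjusted p = 0.122 without the library labelled Control 4 (edgeR, Benjamini-Hochberg). Among 35 apoptosis genes Pmaip1 rose, with 1 higher adjusted over the list alone and camera adjusted p = 0.754. The heat-shock genes Hspa1b and Hsph1 rose 10.7-fold and 4.16-fold among 26 dissociation stress genes, of which 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.505). Hspa1b rose 69.4-fold without Control 1 and had an adjusted p of 0.0836 without the library labelled Control 4, and Samd9l one of 0.053 to 0.0573 without Dnmt1cKO 1, 3 or 5 (edgeR, Benjamini-Hochberg). Control 1 held the highest Control level of Hspa1b, 44.4 CPM, against a Dnmt1cKO mean of 148 CPM.

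Single epithelial identity genes changed, and none of their lists passed camera with all libraries and genotype as the only term. Krt6a and Krt17, keratins of stressed or basal epithelium, rose 12.8-fold and 4.8-fold, and Krt13, a keratin of stratified bladder and mouth epithelium, rose 27.1-fold in spite of 0 counts in Dnmt1cKO 2. Hoxd13, a homeobox gene that patterns the hind end of the body and the genital tract, rose 4.39-fold, from 60.0 ± 30.5 CPM (SD, n = 4) to 265 ± 52.8 CPM (SD, n = 8), with all 8 Dnmt1cKO libraries above all Controls (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.013). Wnt10b, an early marker of prostatic buds, rose 24.4-fold. Psca, a surface protein of bladder and prostate epithelium, Gata3, a transcription factor of urothelium, and Wnt4, a signalling protein, fell 7.54-fold, 2.93-fold and 3.81-fold. Spint2, an inhibitor of cell surface proteases, and Cdh2, N-cadherin, fell 5.6-fold and 7.27-fold, on levels of 3509 CPM for Spint2 in the library labelled Control 4 and 595 CPM for Cdh2 in Control 3. Psca and Wnt4 stood at 765 and 1183 CPM in the library labelled Control 4, and without it they were 1.41-fold and 1.85-fold lower. The log2 fold change of Spint2 without that library was 0.025. Cdh2 was 1.37-fold lower without Control 3. Krt6a and Wnt10b rose 40.6-fold and 92.4-fold without Control 1, and Krt17 rose 7.62-fold without Control 2. The Control left out held the highest Control level of each gene, at 57.9, 4.92 and 110 CPM. The Dnmt1cKO means were 258, 49.2 and 253 CPM.

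In the 24 basal epithelial markers 2 rose and 0 fell, 3 rose and 0 fell adjusted over the list alone, and edgeR gave 6 higher and 2 lower at an unadjusted p under 0.05 (DESeq2 3 and 1, limma-voom 0). The camera adjusted p was 0.129. Among 36 luminal and urothelial markers 1 rose and 2 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.462). Among 37 prostatic bud genes 2 rose and 1 fell, or 2 and 2 adjusted over the list alone (adjusted p = 0.588), and among 40 epithelial adhesion genes 2 fell, or 6 fell and 1 rose adjusted over the list alone (adjusted p = 0.499). Gata3 was the 1 gene that fell among 14 markers of the Wolffian and Mullerian ducts, over all genes and adjusted over the list alone (adjusted p = 0.339). None of 20 androgen and steroid pathway genes was called in edgeR over all genes or adjusted over the list alone; 2 were higher and 3 lower at an unadjusted p under 0.05, DESeq2 called 1 and 2, and limma-voom 0 (camera adjusted p = 0.499). Basal markers passed camera without the library labelled Control 4 (adjusted p = 0.0343), and luminal markers without Control 3 (0.00238) and with the stromal level as a covariate (0.0281). Basal markers (0.0031) and bud genes (0.00055) passed the mixed form of fry. The luminal, bud, androgen and duct lists had a median below 0 and a mean above 0 and were tested as lower, and the adhesion list had a median of 0.089 and a mean of -0.33 and was tested as lower.

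Keratins and regulators of the panel gave values that did not pass the test: the basal factor Trp63 and the basal keratins Krt5 and Krt14 had log2 fold changes of 0.11, -0.12 and 1.06, and the luminal keratins Krt8, Krt18 and Krt7 had -0.48, -1.65 and -0.84. The sign of Trp63 turned with RLE factors (-0.44), and those of Krt5 (0.017) and Krt8 (0.023) with library totals alone. Shh stood at -0.67, Sox9 at -0.61, Foxa1 at 1.02, Cdh1, which encodes E-cadherin, at -1.30 and the uroplakin Upk2 at -2.83. The androgen pathway genes Acsl3 and Fkbp4 had 0.90 and -0.52. Without Control 3 and the library labelled Control 4 the log2 fold changes of Krt8 (0.80), Krt18 (0.66), Upk2 (0.59), Shh (0.061), Sox9 (0.87), Fkbp4 (0.25) and Trp63 (-0.20) had the other sign, as had that of Cdh1 (0.23) without the latter library. Levels in the library labelled Control 4 lay above all other libraries for Krt8, Krt18, Krt7, Cdh1, Shh and Upk2. Several calls among epithelial genes ended without single libraries. Without the library labelled Control 4 the adjusted p was 0.0617 for Krt6a, 0.116 for Krt13, 0.795 for Psca and 0.234 for Wnt4, and Krt13 stood at 0.0589 without Control 3. Krt17 lost its call without any 1 of 10 libraries, Gata3 of 10, Cdh2 of 9 and Spint2 of 8, with adjusted p from 0.0526 to 0.98 (edgeR, Benjamini-Hochberg).

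Markers of stroma, nerves and blood vessels were lower in Dnmt1cKO as lists. Stromal markers, which are collagens and other genes of fibroblasts and smooth muscle, had a median log2 fold change of -1.32 over 36 members (camera adjusted p = 2.43e-11; adjusted p = 0.412 with an estimated correlation). Neural and glial markers had a median of -1.34 over 20 members (adjusted p = 2.04e-06; adjusted p = 0.412 with an estimated correlation), and endothelial markers one of -0.54 over 14 (adjusted p = 0.0316; adjusted p = 0.412 with an estimated correlation). Elavl3, an RNA-binding protein of neurons, was the 1 neural gene that fell, 15.7-fold, with 2 lower adjusted over the list alone. It was 8.58-fold lower with adjusted p = 0.266 without the library labelled Control 4 and 28.8-fold lower without Dnmt1cKO 4 (edgeR, Benjamini-Hochberg), and it lost its call without any 1 of 8 libraries. None of the stromal markers was called in edgeR over all genes or adjusted over the list alone, with 11 lower at an unadjusted p under 0.05, 3 lower in DESeq2 and 1 in limma-voom. None of the endothelial markers was called over all genes in edgeR, 1 fell adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05, with 1 in DESeq2 and 0 in limma-voom. The collagens Col1a1 and Col3a1 had log2 fold changes of -1.67 and -0.88, and the endothelial genes Egfl7 and Kdr -3.61 and -3.42. The sign of Egfl7, highest in the library labelled Control 4 (301 CPM), turned with limma-voom (0.20). With the stromal level as a covariate those of Col3a1 (0.19) and of Kdr (0.28), highest in Control 3 (100.3 CPM), turned.

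The stromal level varied widely within each group. Its mean log2 CPM was 5.93, 5.80 and 6.50 in Controls 1 to 3 and 2.72 in the library labelled Control 4, and 2.38 to 5.33 in the Dnmt1cKO libraries. Stromal markers were lower in Dnmt1cKO for 33, 26, 30 and 13 of 36 members within the codes 4, 5, 6 and 7, and for 10 in all of them; neural markers were lower for 19, 1, 15 and 9 of 20, and for 0 in all of them. With the stromal level as a covariate 122 genes rose and 243 fell, of which 109 and 156 were among the 132 and 198, and 25 germline genes rose. Of 16 immune cell markers none was called in edgeR over all genes or adjusted over the list alone (1 higher and 2 lower at an unadjusted p under 0.05, the same counts in DESeq2, 0 in limma-voom); their median (0.38) and mean (0.29) lay above 0 while camera tested them as lower (adjusted p = 0.931). Lcp1 and Cx3cr1, genes of leukocytes, had 0.41 and -2.35. The sign of Cx3cr1 turned with limma-voom (0.93), in Control 1 against 7 Dnmt1cKO libraries (0.59) and without Control 3 and the library labelled Control 4 (1.48), where that of Lcp1 turned too (-0.48). Of 5 erythroid markers none was called in edgeR over all genes or adjusted over the list alone (1 lower at an unadjusted p under 0.05 and in DESeq2, 0 in limma-voom; camera adjusted p = 0.0932), with Hba-a2 and Hbb-bs, near-identical to other globin copies, at -2.58 and -1.82, the latter 0.54 with the stromal level as a covariate. Of 4 hindgut markers tested none was called in edgeR or the other tools, 2 rose adjusted over the list alone and 2 were higher at an unadjusted p under 0.05; Hnf4a and Krt20 had no count in Control and were at least 11.1-fold and 12.3-fold higher in the mean without passing the test over all genes.

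Imprinted genes, which are expressed from 1 parental allele under the control of DNA methylation, did not pass camera as a list with all libraries and genotype as the only term (adjusted p = 0.122). They passed as lower without the library labelled Control 4 (0.0185) and with codes 4 to 7 alone (0.0338). Their mean log2 CPM was 2.62 in the library labelled Control 4 and 4.85 to 5.10 in the other Controls. Cdkn1c, a cell cycle inhibitor expressed from the maternal allele (chromosome 7, 143458339 to 143461050), fell 3.06-fold, from 1139 ± 852 CPM (SD, n = 4) to 373 ± 170 CPM (SD, n = 8; edgeR with Benjamini-Hochberg adjusted p = 0.02), and was 1.94-fold lower with an adjusted p of 0.226 without Control 3. Igf2, a paternally expressed growth factor, had a log2 fold change of -1.38 and adjusted p = 0.0748 in the same test. Of 34 imprinted genes tested 1 fell, or 2 adjusted over the list alone, with a median of -0.27 and a mean of 0.25, while camera tested them as lower. Among the 25 genes of the DNA methylation machinery none was called in edgeR over all genes or adjusted over the list alone; 1 was higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 3 lower and limma-voom 0 (camera adjusted p = 0.506). Uhrf1, the partner that brings Dnmt1 to replicated DNA, the de novo methyltransferases Dnmt3a and Dnmt3b, and the DNA glycosylase Tdg had log2 fold changes of -0.83, -0.85, 0.22 and 0.21, and that of Tdg was -0.38 with RLE factors. The sign of Uhrf1 turned with limma-voom (0.55), without Control 3 and the library labelled Control 4 (0.81) and in Control 1 against 7 Dnmt1cKO libraries (0.85), and that of Dnmt3b without Control 2 (-0.21), the library labelled Control 4 (-0.056) or Dnmt1cKO 6 (-0.092). None of 20 clustered protocadherins, adhesion proteins of neurons with methylated promoters, was called in edgeR over all genes or adjusted over the list alone; 3 were higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 1 higher and limma-voom 0 (median 0.80, camera adjusted p = 0.597). Pcdhga9 and Pcdha2, whose clusters share exons, had -0.65 and 0.85, and Pcdhga9 had 0.24 without Control 3 and 0.55 with the stromal level as a covariate.

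Of the Y-linked genes, Ddx3y stood at 76.1 to 188 CPM in Control and 78.3 to 212 CPM in Dnmt1cKO, a log2 fold change of -0.19 that was 0.044 with library totals alone, and it was present in every library. Usp9y, which lies beside Ddx3y on the Y chromosome, had no count in Control and 1.141 to 46.0 CPM in Dnmt1cKO, at least 57-fold higher (edgeR with Benjamini-Hochberg adjusted p = 0.0163, and 0.0515 without the library labelled Control 4). It was the 1 sex-linked gene of 5 tested that was called.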

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

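The counts over other splits of the libraries were planned before the data were examined, as was the fit with the stromal level as a covariate. All other tests in this part, those of carried-over gonadal tissue, lost low transcripts, shared reads, Control library complexity and remaining Dnmt1, were chosen after the result they bear on was seen. The use of the stromal fit to weigh a source of the lower genes was also chosen afterwards.

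Germline genes were higher in Dnmt1cKO, and 3 technical sources were weighed. Carry-over of gonadal tissue was argued against as the whole source by its markers. Their median Dnmt1cKO level was 0% of that of the 26 called germline genes (0 against 44.9 CPM). Of 28 markers, 2 of them in another list, 20 lay under 1 CPM, and none of 6 tested was called in edgeR. Pou5f1, Dppa3, Nanos2, Amh, Insl3 and Cyp17a1 had no count. Kit (36.1 CPM), Tfap2c (20.9 CPM) and Nanog were highest, and other tissues also express Kit and Tfap2c. Nanog stood at 13 ± 18.8 CPM in Dnmt1cKO (SD, n = 8) against 5.21 CPM in Control. Its log2 fold change of 1.24 did not pass the test (edgeR, Benjamini-Hochberg adjusted p = 0.661). Kit and Prdm1 also had a positive log2 fold change, and Tfap2c, Inha and Fst a negative one. The level of Nanog goes in the direction of carry-over, so a small contribution was not excluded. Loss of low transcripts from the Control libraries was argued against by level-matched genes, since 44.4% of the germline genes with at least 10 CPM in Dnmt1cKO (16 of 36) had at most 3 Control counts, against at most 8.33% in 1000 draws of genes with similar Dnmt1cKO levels. Reads shared between copies were argued against as the whole source, since the list without multi-copy families kept camera adjusted p = 7.88e-20, a median log2 fold change of 6.63 and 17 called genes of 40 (adjusted p = 0.0336 with an estimated correlation). That loss of Dnmt1 raised these genes stays a hypothesis, found and tested on the same libraries, and methylation was not analysed here.

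The 198 genes lower in Dnmt1cKO all peaked in Control 3 or the library labelled Control 4. Without these libraries their median log2 fold change went from -2.35 to -0.60 and none was called in edgeR. Genes called with a library shrink without it by selection, so this decides nothing. Over all genes, edgeR with Controls 1 and 2 against the 8 Dnmt1cKO libraries called 2 lower and 45 higher, and with the other 5 pairs of Controls 53 to 1238 lower and 32 to 2990 higher. Low complexity of Control 3 and the library labelled Control 4, whose single Dnmt1 count goes against its label, may be a source. But calls in both directions varied with the pair kept, so low complexity cannot be told apart from a fall due to genotype. Less stroma in Dnmt1cKO was argued against as the whole source, since 156 of the 198 stayed called lower with the stromal level as a covariate.

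Dnmt1 transcript remained in every Dnmt1cKO library. Carried-over stroma, in which Shh-driven Cre is not active, may be its source, but over the 8 Dnmt1cKO libraries Dnmt1 and the stromal level correlated with Pearson's r = 0.448 (exact permutation p = 0.254) and Spearman's rho = 0.429 (exact permutation p = 0.299), and with r = 0.619 over 6 libraries without the extremes (exact permutation p = 0.186), so stroma and transcripts that lack the deleted part cannot be told apart with 8 libraries. Between the groups, the stromal level as a covariate took the log2 fold change of Dnmt1 from -1.29 to -0.024; the library labelled Control 4 is low in both. A deletion that removed only part of the gene, or only reached part of the cells, was not tested. No biological explanation of the single Dnmt1 count in the library labelled Control 4 was tested, and Taf7l, Dazl and Tex19.1 were at 0 there, and below every Dnmt1cKO library in the other Controls too. Of the Y-linked genes tested, Eif2s3y, Kdm5d and Uty also stood at 2.84 CPM there and Usp9y at 0, while Ddx3y stood at 179 CPM. A low level of a single gene in that library therefore does not decide its label.

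Among 100 splits of the 12 libraries, the real one included, 2 gave as many changed genes as the real 330 (highest other 514). As many higher genes as 132 came from 2 splits (highest other 352), and as many lower genes as 198 from 2 (highest other 274). The median of the other splits was 0. Each share lay under the 0.05 limit fixed beforehand. The splits treat the libraries as interchangeable, which Control 3 and the library labelled Control 4 are not. The shares therefore do not tell genotype from library quality. The split with 514 genes put Controls 2 and 3, the library labelled Control 4 and Dnmt1cKO 2 together, the 4 libraries with the fewest genes detected; it called 6 germline genes higher and points to a structure of the samples besides genotype. The split with 274 lower genes put Control 1, Control 3, the library labelled Control 4 and Dnmt1cKO 8 together. Camera p-values as low as the real one came from 1 split for germline genes (4.26e-31, lowest other 1.46e-25) and 2 for p53 targets (5.94e-05, lowest other 4.86e-05), both under that limit. These p-values use the preset correlation. With an estimated correlation p53 targets did not pass (camera, Benjamini-Hochberg adjusted p = 0.412). Chance cannot be excluded for interferon-stimulated genes (10 splits, 0.0139 against 0.000972), proliferation genes (30 splits, 0.00903 against 2.65e-05), stromal markers (24 splits, 2.31e-12 against 5.5e-44), endothelial markers (13 splits, 0.00821 against 1.81e-06) and neural markers (28 splits, 2.92e-07 against 3.13e-22).

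Single libraries stood far from the rest of their group by Dixon's ratio in 28 of 210 combinations of a measure and a group. Chance marks about 1 in 20 of those that can be tested. The 210 include Control groups with every library at 0, which could not be tested. Dnmt1cKO 2 stood apart 12 times, Dnmt1cKO 8 6 times, the library labelled Control 4 5 times, Control 3 4 times and Dnmt1cKO 7 1 time. In the library labelled Control 4, Dnmt1 stood at 2.84 CPM (114 to 237 in other Controls), Samd9l at 2.84 (0; a single count, against which the ratio is fixed at its maximum), Spint2 at 3509 (151 to 210) and Col3a1 at 245 (1783 to 2212), and imprinted genes had a mean log2 CPM of 2.62 (4.85 to 5.10). In Control 3, D3Bwg0562e stood at 295 CPM (17.1 to 20.2), Trp63 at 2.26 (230 to 250), Foxa1 at 2.26 (45.5 to 78.1) and Ddx3y at 76.1 (179 to 188). In Dnmt1cKO 2, Zscan4d stood at 0.224 CPM (23.8 to 347 in other Dnmt1cKO libraries), Pet2 at 7.41 (19.5 to 44.7), Tef at 0.673 (5.96 to 26.2), Krt17 at 29.6 (188 to 378), Krt13 at 0 (38.7 to 254) and Krt8 at 1826 (628 to 972). This library also had 10205 genes with a count (12735 to 13837) and low mean log2 CPM of the methylation machinery (4.82; 5.63 to 6.06), repair genes (4.54; 5.02 to 5.31), apoptosis genes (4.25; 4.91 to 5.13), prostatic bud genes (3.14; 4.51 to 4.92) and duct markers (-0.58; 2.41 to 4.45). In Dnmt1cKO 8, Clca4 stood at 1.141 CPM (15.9 to 75.9), Cdkn1a at 12.3 (53.5 to 122), Pcdha2 at 7.42 (30.3 to 71.4), Hsph1 at 132 (259 to 421) and Mki67 at 246 (409 to 614), and its 50 most abundant genes took 19% of counts (12.8 to 15.7%). In Dnmt1cKO 7, Amer1 stood at 14.1 CPM (23.7 to 35.5).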

How the results depend on the processing

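The alternatives without Control 3 and the library labelled Control 4, and with Control 1 alone against 7 Dnmt1cKO libraries, were chosen after the data were examined; the others were planned. Depth and spread limit what can be called: the coefficient of variation between libraries was 0.984, and edgeR recovered 10.4% of simulated 4-fold changes. The cause was not tested for any changed result in this part, apart from the smaller number of libraries where libraries were left out. The germline list kept its direction and stayed past the threshold under all alternatives. The 132 higher genes kept their sign in edgeR, DESeq2 and limma-voom under each of them, and of the 198 lower genes 139 did so in Control 1 against 7 libraries and 174 without Control 3 and the library labelled Control 4. Both sets were called from the same libraries, and 88 of the 132 had at most 3 counts over the Controls. Selection largely set these signs, so they give no separate support. Dnmt1 was lower and not called under each alternative (edgeR, DESeq2 or limma-voom, Benjamini-Hochberg adjusted p 0.0815 to 0.992), with a log2 fold change of -1.60 to -0.84 when 1 library was left out and -0.024 with the stromal level as a covariate. Over all named genes and alternatives, 1881 values kept direction and side of the threshold, 257 lost a call, 25 gained one and 70 changed sign. Of 44 named genes called, 24 lost the call without 1 library, 21 of them without the library labelled Control 4.

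Against 132 higher and 198 lower genes (330 in all), DESeq2 called 487 and 1030 (1517), limma-voom with quality weights 7 and 25 (32), RLE factors 170 and 726 (896), library totals alone 113 and 47 (160), a test against a 1.5-fold change 106 and 79 (185), and codes 4 to 7 alone 114 and 56 (170). Without Control 3 and the library labelled Control 4 the numbers were 45 and 2 (47), and in Control 1 against 7 libraries, where the lone Control is assumed to vary like the other group, 46 and 0 (46). Leaving out 1 library gave 60 to 657 higher, 36 to 494 lower and 96 to 1151 changed genes, lowest without the library labelled Control 4 and highest without Control 1. Apart from the replicate blocks, given last, the other alternatives stayed within 1.5 times: no filter (136 and 213), a stricter filter (132 and 204), unrounded counts (132 and 198), code 7 summed (105 and 148) and the stromal covariate (122 and 243). A minimum log2 change of 1 removed no call.

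List tests gave these Benjamini-Hochberg adjusted p-values from camera where a list changed side or direction. With DESeq2 statistics proliferation genes stood at 0.224, endothelial markers at 0.306 and immune markers, turned, at 0.987. With limma-voom the direction turned for the methylation machinery and apoptosis genes (0.889 each), adhesion genes (0.289) and immune markers (0.189), and erythroid markers passed (0.000829). RLE factors gave 0.1004 for proliferation genes and for endothelial markers, and 0.894 for immune markers, turned. Interferon-stimulated genes stood at 0.0604 with library totals alone, 0.0513 without the filter, 0.0506 without genes of more than 1 list and 0.313 with the stromal covariate; erythroid markers passed without the filter (0.0127). With codes 4 to 7 alone imprinted genes (0.0338) and erythroid markers (0.00589) passed and proliferation genes did not (0.11). With code 7 summed immune markers turned (0.718). With the stromal covariate luminal markers passed (0.0281), endothelial markers did not (0.421), and immune markers (0.866) and dissociation stress genes (0.915) turned. With an estimated correlation p53 targets, stromal, endothelial and neural markers (0.412 each), interferon-stimulated genes (0.418) and proliferation genes (0.697) did not pass.

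Fry, which does not compare a list with other genes, gave 0.225 for stromal, 0.374 for endothelial and 0.245 for neural markers, and the other direction for imprinted genes and duct markers (0.966 each), the methylation machinery and bud genes (0.268 each), luminal markers (0.685), androgen pathway genes (0.401), adhesion genes (0.377) and immune markers (0.245). Its mixed form gave 0.111, 0.49 and 0.102 for stromal, endothelial and neural markers, and repair genes (0.0209), apoptosis genes (0.00195), basal markers (0.0031), bud genes (0.00055) and dissociation stress genes (0.000325) passed it. Without Control 3 and the library labelled Control 4, endothelial markers stood at 0.0897, and apoptosis (0.909), bud (0.962), androgen pathway (0.947), adhesion (0.717) and immune lists (0.256) turned. In Control 1 against 7 libraries the methylation machinery (0.889), luminal (0.607), bud (0.84), adhesion (0.0708), immune (0.276) and duct lists (0.84) turned, and erythroid markers (0.013) and dissociation stress genes (0.0136) passed. Without 1 library the camera adjusted p ranged from 5.22e-36 to 1.78e-14 for germline genes, 0.0221 to 0.289 for interferon-stimulated genes, 0.00503 to 0.112 for proliferation genes, 0.00669 to 0.129 for endothelial markers, 0.0216 to 0.311 for erythroid markers, 0.0185 to 0.716 for imprinted genes, 0.0343 to 0.754 for basal markers, 0.00238 to 0.623 for luminal markers, 0.0774 to 0.988 for repair genes, 0.477 to 0.84 for apoptosis genes, 0.376 to 0.787 for bud genes, 0.179 to 0.623 for adhesion genes and 0.396 to 0.996 for immune markers. Interferon-stimulated genes and endothelial markers lost the threshold without Control 1, Control 3 or Dnmt1cKO 3, 5, 6 or 7, and proliferation genes without Control 1, the library labelled Control 4, Dnmt1cKO 2 or 7. Without the library labelled Control 4 imprinted genes and basal markers passed, and repair, apoptosis, luminal, bud and adhesion lists turned. Luminal markers passed without Control 3 and erythroid markers without Dnmt1cKO 2, and immune markers turned without Control 3, Dnmt1cKO 6 or 7.

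Log2 fold changes of named genes that changed sign were, with DESeq2, Tdg -0.37 and Trp63 -0.45; with RLE factors, Tdg -0.38 and Trp63 -0.44. With limma-voom they were Egfl7 0.20, Cx3cr1 0.93, Uhrf1 0.55, Krt8 0.43, Krt18 0.17, Upk2 0.65, Shh 0.19 and Sox9 0.49, and with library totals alone Hmgb2 0.15, Krt5 0.017, Krt8 0.023 and Ddx3y 0.044. With codes 4 to 7 alone they were Hmgb2 0.079, Lcp1 -0.0055 and Krt5 0.0054, and with the stromal covariate Pcdhga9 0.55, Col3a1 0.19, Kdr 0.28, Hbb-bs 0.54 and Trp63 -0.15. Without Control 3 and the library labelled Control 4 they were Hmgb2 0.18, Fkbp4 0.25, Spint2 0.067, Cdh2 0.52, Lcp1 -0.48, Cx3cr1 1.48, Uhrf1 0.81, Trp63 -0.20, Krt8 0.80, Krt18 0.66, Upk2 0.59, Shh 0.061 and Sox9 0.87. In Control 1 against 7 libraries they were Hmgb2 0.24, Lig1 0.25, Fkbp4 0.21, Spint2 0.30, Cx3cr1 0.59, Uhrf1 0.85, Trp63 -0.21, Krt8 0.71, Krt18 0.70, Sox9 0.95 and Cdh1 0.49. Of these genes Spint2, Cdh2 and Lig1 were called with all libraries. Without 1 library the range crossed 0 for Dnmt3b (-0.21 to 1.51), Krt5 (-0.42 to 0.52), Pcdhga9 (-0.94 to 0.24), Hmgb2 (-0.25 to 0.032), Lcp1 (-0.016 to 2.21), Trp63 (-0.30 to 0.37), Top2a (-0.12 to 1.10), Mki67 (-0.060 to 0.83), Spint2 (-2.85 to 0.025), Krt8 (-0.75 to 0.58), Upk2 (-3.80 to 1.09), Shh (-1.07 to 0.62) and Cdh1 (-1.64 to 0.23).

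The groups share the title numbers and part of the b codes. Deviations from the group means correlated at -0.0524 to 0.0959 in the 4 pairs with the same title number and at -0.0522 to 0.061 in the 6 pairs with the same code, so neither was taken to pair the samples. Title numbers 5 to 8 and codes 2 and 3 occur in Dnmt1cKO alone. As blocks they take up Dnmt1cKO 5 to 8, or Dnmt1cKO 1 and 2, which then add nothing to the contrast. Fewer libraries therefore bear on the calls with either block. With the title number as a block 34 genes rose and 31 fell (65 in all), endothelial markers stood at adjusted p = 0.109 and immune markers turned (0.5261, camera with Benjamini-Hochberg adjustment), and Pcdhga9 (0.024), Krt8 (0.047) and Shh (0.69) had a positive log2 fold change. With the code as a block 135 rose and 72 fell (207 in all), proliferation genes stood at 0.0689, luminal (0.0247) and erythroid markers (0.00718) passed camera, immune markers turned (0.817), and Pcdhga9 (0.057) and Krt5 (0.26) had a positive log2 fold change.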

Other observations

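The counts and tests in this part were all chosen after the values were seen. Of 21 tested genes known from the 2-cell embryo stage, 13 were called higher and 0 lower in edgeR (quasi-likelihood, Benjamini-Hochberg) and 8 did not pass. The list was put together from values already seen, so it was not tested as a group. Zscan4f stood at 370 ± 296 CPM in Dnmt1cKO (SD, n = 8) and BC061212 at 88.1 ± 91.5 CPM, against 0.468 CPM and 0 in Control, and their levels spread widely between Dnmt1cKO libraries, from 0 in at least 1. The Zscan4, Usp17l, Tcstv and Pramef families hold near-identical copies, so levels of single members are uncertain. The homeobox genes of the Rhox cluster and the Xlr family, both X-linked, gave 14 higher and 1 lower gene of 27 tested, Rhox6 at 69.1 ± 14.6 CPM (SD, n = 8) against 1.35 CPM in Control; the lower gene was Rhox8, which fell from 168 to 4.87 CPM, 34.8-fold with all libraries and 15.5-fold without Control 3. Of 20 genes of the amino acid stress response 2 rose, Asns, which makes asparagine, at 49.0 ± 34.3 CPM (SD, n = 8) against 1.11, and Trib3, a pseudokinase induced by stress, at 9.43 ± 6.78 CPM (SD, n = 8) against 0. The other 18 did not pass, among them Atf4 and Ddit3 with log2 fold changes of -1.45 and -3.36. Of the 20 genes, 16 had a positive log2 fold change. This list too was not tested as a group.

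Genes on the X chromosome made up 24 of the 130 higher genes with a known chromosome, an odds ratio of 5.93 against other tested genes (Fisher's exact 95% interval 3.6 to 9.41, p = 1.17e-10), and 11 of 196 lower genes (odds ratio 1.51, interval 0.734 to 2.78, Fisher's exact p = 0.186). Genes with the same name stem and chromosome were then counted as 1, and as higher where any member was called. The odds ratio for higher genes was then 3.13 (11 of 108, interval 1.5 to 5.91, Fisher's exact p = 0.00161). A family with many members has more chances to count as higher, so the influence of family size was only partly removed. A hypothesis in line with this test is that X-linked genes may respond to the loss of Dnmt1 more often than others; the X chromosome is known to hold many germline genes, which this test does not separate from the rest.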
